A study of Homo sapiens with 4 samples.

How the data were processed

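Gene expression was measured on 4 Affymetrix arrays, each with 1 sample of total RNA from an established human head and neck squamous cell carcinoma line. OECM1 cells carried a lentiviral short hairpin against TCF12 or a hairpin against luciferase as control. HSC3 cells carried a retroviral vector with the TCF12 coding sequence or the vector alone (VA). Per the labels, infected cells were selected with puromycin, RNA was extracted with TRIzol, and biotin-labelled RNA was hybridised by the standard Affymetrix protocol. There was 1 array per group, so no value has a replicate error, and the number of arrays limits the precision.

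The deposited values were a linear intensity per probe set and array, from the authors' value table. The software that summarised the probes and scaled the arrays is not given in the sources used here. The values had 1 decimal, were never negative, and had a mean without the highest and lowest 2% of 500.1 on each of the 4 arrays, a sign of scaling to a common level. The median intensity lay between 82.7 and 89.2. Maximum intensity was 64641 in OECM1 shluc, 65148 in OECM1 shTCF12, 64228 in HSC3 VA and 49413 in HSC3 TCF12. A scaling to a common mean takes no account of a difference in the shape of the bright range, which can move bright genes as a class.

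Of 54675 probe sets, 62 were Affymetrix controls, 41097 had 1 gene symbol, 1801 had several and 11715 had none in the platform annotation used. Probe sets with several symbols or none were not assigned to a gene. Gene identifiers were matched to NCBI RefSeq names of assembly GRCh38.p14, which held 99.9% of the probe sets with 1 symbol. This gave 19777 genes. A gene was represented by its probe set with the highest mean over the 4 arrays. Intensities were transformed as log2(intensity + 16), and differences and folds are on that scale, which understates the fold of dim genes.

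A gene counted as measured in a pair of arrays if it lay above the 40th percentile of the array's probe sets (the floor, an intensity of 53.8 to 55.9) on at least 1 of the 2 arrays. Where the dimmer array lay below the floor, the fold was computed against the floor and is given as a lower bound. KYNU, LUM, OAS1 and KRT14 in OECM1 shluc and CD163L1 and H4C8 in HSC3 VA lay above the floor by less than 10%, so the size of their differences is uncertain. Genes with a difference of at least 2-fold were counted without a p-value. The counts use the log2 difference itself, not the lower bound, so they can include genes whose lower bound is under 2-fold. The genes named for each pair were the 10 with the largest positive and the 10 with the largest negative difference, provided that the brighter array lay above the 60th percentile and that all measured probe sets of the gene went the same way. The same rule, applied to the smaller of both differences, named genes that moved oppositely with knockdown and overexpression. Up to 4 members per gene list were named by size of difference, and any member of the lists of E and ID proteins, epithelial genes, mesenchymal genes and transcription factors of epithelial-mesenchymal transition could be named. This rule, the 29 gene lists and the comparisons were fixed before the data were examined.

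For each list the median log2 difference of its measured members was set against 10000 random lists of the same size, matched in 20 bins of mean expression. A list below the 2.5th or above the 97.5th percentile is said to stand apart, a description of these arrays rather than of replicated conditions. On simulated data with no shift, 5 of 100 lists stood apart in the knockdown pair and 4 of 100 in the overexpression pair. With 30 members shifted by 0.3 log2, 92 and 93 of 100 stood apart. These simulations shuffled the differences over genes and drew members at random, so they hold no co-regulation within a list. Lists of co-regulated genes can stand apart more often than such draws, between any cultures. A common effect of TCF12 over both lines was fitted with limma 3.58.1 (R 4.3.3) as cell line plus intended TCF12 level, with an intensity trend in the prior and Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom and treats knockdown and overexpression as repeats of a single contrast. On simulated data for this model, on 15756 genes, it recovered 10 of 50 genes altered 2-fold, 35 of 50 altered 4-fold and 49 of 50 altered 16-fold, with 20 false calls. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

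Alternatives were median centring, quantile normalization, a pseudocount of 1 or 64, no filter or a 60th percentile filter on low values, the mean of a gene's probe sets, leaving out probe sets of the _s_at and _x_at type that can bind several transcripts, thresholds of 1.5-fold and 3-fold, and limma without the trend or with a robust prior. Leaving out genes above an intensity of 20000, using 100 expression bins and leaving TCF12 out of its lists were added after the data were seen.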

Results

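The data were 4 expression arrays from OECM1 and HSC3, oral squamous cell carcinoma lines, with 1 array for each of OECM1 shluc, OECM1 shTCF12, HSC3 VA and HSC3 TCF12. They address which transcripts differ when TCF12, a basic helix-loop-helix transcription factor of the E protein family, is reduced in OECM1 or expressed from a vector in HSC3. With 1 array per group, no difference has a replicate check, and no p-value is given for a single pair. Differences below are log2 values of the manipulated cells minus their control.

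TCF12 was lower in the hairpin cells and little different in the vector cells. The brightest of the 4 TCF12 probe sets had an intensity of 1480 in OECM1 shluc and 786.3 in OECM1 shTCF12, which is 53.1% of the control (log2 difference -0.90). A dimmer probe set gave 144.8 and 80.5, or 55.6%. In HSC3, the brightest probe set had 1561 in VA and 1754 in TCF12 cells, 112% of the control (0.17), and that dimmer probe set had 178.1 and 224.2, 126% (0.31). The other probe sets, both near the level of the dimmer one, differed by at most 0.025 in either line. The mean over the 4 probe sets differed by -0.41 in OECM1 and 0.13 in HSC3. The vector carried the coding sequence alone, and where these probe sets lie in the transcript is not given in the sources used here. A probe set outside the coding part would not detect the vector transcript, so the arrays leave the level of vector-derived TCF12 open.

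**Figure D1:**
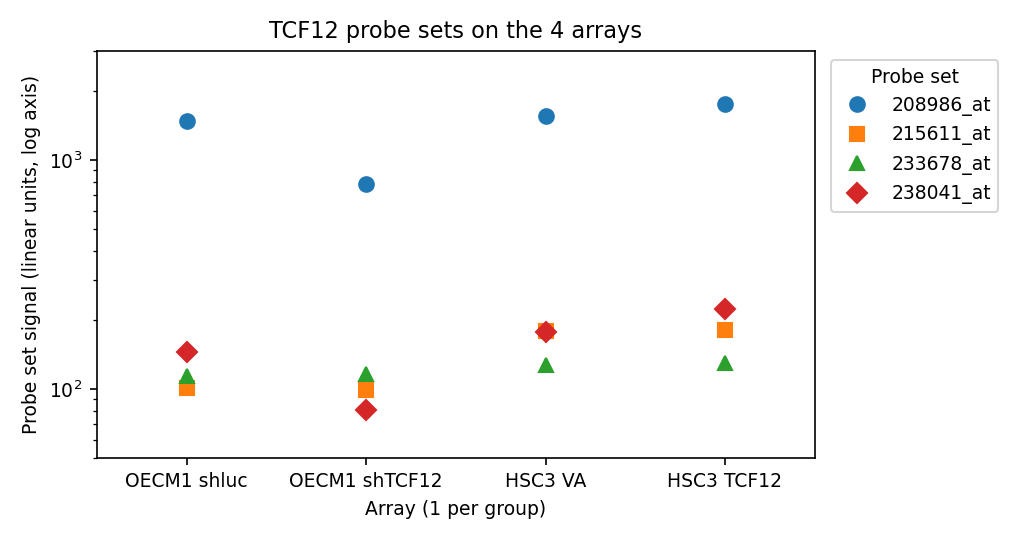
Intensity of the 4 TCF12 probe sets (log axis) on each array, 1 point per array. The intensity of the brightest was 1480 in OECM1 shluc, 786.3 in OECM1 shTCF12, 1561 in HSC3 VA and 1754 in HSC3 TCF12.

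OECM1 shTCF12 cells had higher transcript levels of inflammatory and interferon-stimulated genes than OECM1 shluc cells, and lower levels of epithelial junction genes. The list of basal keratinocyte genes was also higher, although its keratin genes KRT5 and KRT14 stayed dim. EHF, an epithelial transcription factor of the ETS family, was 26.8-fold higher, with all 6 of its measured probe sets higher. TNC, the matrix glycoprotein tenascin C, was 21.6-fold higher, and KYNU, the tryptophan-degrading enzyme kynureninase, was 18.9-fold higher. S100A9, a subunit of calprotectin, was at least 19.6-fold higher, and the methyltransferase gene NNMT at least 12.7-fold. The complement protease gene C1S was at least 8.68-fold higher, the thrombin receptor gene F2RL2 at least 7.53-fold, the cobalamin-binding protein gene TCN1 at least 5.94-fold, S100A8 at least 5.69-fold and the annexin gene ANXA10 at least 4.23-fold.

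Lower in OECM1 shTCF12 were ALPP, placental alkaline phosphatase, by 10.3-fold, its close relative ALPG by 4.45-fold, and PSG7, of the pregnancy-specific glycoprotein family, by 7.12-fold. SLC7A7, an amino acid transporter subunit, was 7.93-fold lower, and INHBB, the inhibin beta B subunit, was 7.84-fold lower. The kallikrein gene KLK5 was 4.91-fold lower, the neurexin gene NRXN3 4.12-fold, the matrix protein gene NPNT 4.10-fold, the homeobox gene HOXC13 3.99-fold and HABP4 3.97-fold. Of 14365 measured genes, 821 were at least 2-fold higher and 430 at least 2-fold lower. With the floor at the 60th percentile these counts were 409 and 123. S100A8, HABP4, KYNU, C1S, SLC7A7, PSG7, KLK5, ALPG and HOXC13 rest on probe sets that can bind several transcripts. The ALPG value may therefore not be separate from that of ALPP. For S100A8 and HABP4, the other type of probe set lay below the floor on both OECM1 arrays.

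Inflammatory genes gave the highest list median in the knockdown pair. Of 31 measured genes of NF-kB and inflammatory cytokines, 19 were at least 2-fold higher, 0 were at least 2-fold lower and 2 lay below 0. Their median was 1.45 against a random range of -0.11 to 0.20. Among them the chemokine gene CXCL8 was higher by 3.70, the complement gene C3 by 3.63, and PTX3 and IL1A at least 3.73-fold and 2.70-fold. Of 46 interferon-stimulated genes, 20 were at least 2-fold higher, 0 were at least 2-fold lower and 3 lay below 0 (median 0.90). The higher ones included IFI44L at 3.63, IFI27 at 2.92 and OAS1 at 2.80, with BST2 at least 5.74-fold higher. Antigen presentation genes had a median of 0.58, with NLRC5 at 1.56 and ERAP2 at 1.42. That list no longer stood apart without probe sets that can bind several transcripts, at 0.26.

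Several other lists stood apart on the higher side in OECM1 shTCF12. Keratinocyte basal layer genes had a median of 0.60 over 15 members, 11 of them above 0, with the integrin gene ITGB4 at 1.98. The keratin gene KRT14 had intensities of 54.9 in OECM1 shluc and 47.5 in OECM1 shTCF12, and KRT5 had 54.5 and 97.8. NRF2 targets, genes of the oxidative stress response, had a median of 0.41 over 24 members, led by the reductase gene AKR1B10 at 3.34 and the transporter gene ABCC3 at 2.88. Matrix proteases and inhibitors had a median of 0.42, with ADAM12 at 1.39 and ADAM10 at -1.40. ERK pathway feedback genes had 0.29, with DUSP6 at 1.69 and ETV5 at 1.54. Replication-dependent histones had 0.59 over 11 members, with H2AC6 at 1.22. p53 targets had 0.25, with CDKN1A at 1.32 and FAS at 1.14, a shift that was absent (-0.01) without probe sets that can bind several transcripts. Fibroblast markers, fixed as a sign of another cell type and all also in the mesenchymal list, had a median of 0.92 over 7 measured members. Of these, 6 lay above 0, with LUM at 3.85, FAP at 2.20 and POSTN at 1.66, and 1 below. Leukocyte markers, fixed for the same purpose, had 0.03 over 4 measured members, inside their random range.

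Epithelial genes were lower as a group in OECM1 shTCF12, and mesenchymal genes split. Of 38 epithelial junction and identity genes, 30 lay below 0 (median -0.36, random range -0.09 to 0.11). The tight junction gene OCLN was at -1.51, TJP1 at -0.84 and CLDN7 at -0.92, and the E-cadherin gene CDH1 at -0.39, while CLDN1 was at 2.06. Of 35 mesenchymal markers, 11 were at least 2-fold higher and 1 at least 2-fold lower. The 11 include BGN, whose lower bound was 1.58-fold, and COL6A1 and MMP2, whose values turned under an alternative. TNC was at 4.44, LUM at 3.85 and VIM, encoding vimentin, at 3.65, while FN1, encoding fibronectin, was at -1.36. The mesenchymal median was -0.03, inside the random range, and 0.39, outside it, with the mean of a gene's probe sets. ZEB1, a repressor of epithelial genes, was at least 4.15-fold higher, SNAI2 was at 0.49 and TWIST1 at 0.66. The list of such transcription factors had a median of 0.17, inside its random range, and 0.33, outside it, without TCF12.

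The list of E and ID proteins, which holds TCF12 itself with partners and inhibitors of its family, had a median of -0.41 in OECM1 shTCF12, with 10 of 14 members below 0, and -0.39 without TCF12. ID2 was at -1.24, ID3 at -1.15, ID1 at -0.43, TCF4 at -0.71 and TCF3 at -0.19, while BHLHE40 was at 1.04, TWIST1 at 0.66 and BHLHE41 at 0.51. BMP targets, which share the ID genes, had -0.32, with GATA2 at -1.40, SMAD7 at -1.24 and RUNX2 at 1.99. Cell cycle genes were lower by small amounts: 32 of 41 genes of G1/S and DNA replication lay below 0 (median -0.16) and 42 of 48 genes of G2/M and mitosis (median -0.18), with E2F1 at -0.80 and KIF14 at -0.89, while CHAF1B was at 0.58. In all, 15 of 28 lists stood apart, where 1.4 would with members drawn at random. The E and ID protein and BMP lists no longer stood apart without probe sets that can bind several transcripts, at -0.31 and -0.10.

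**Figure D2:**
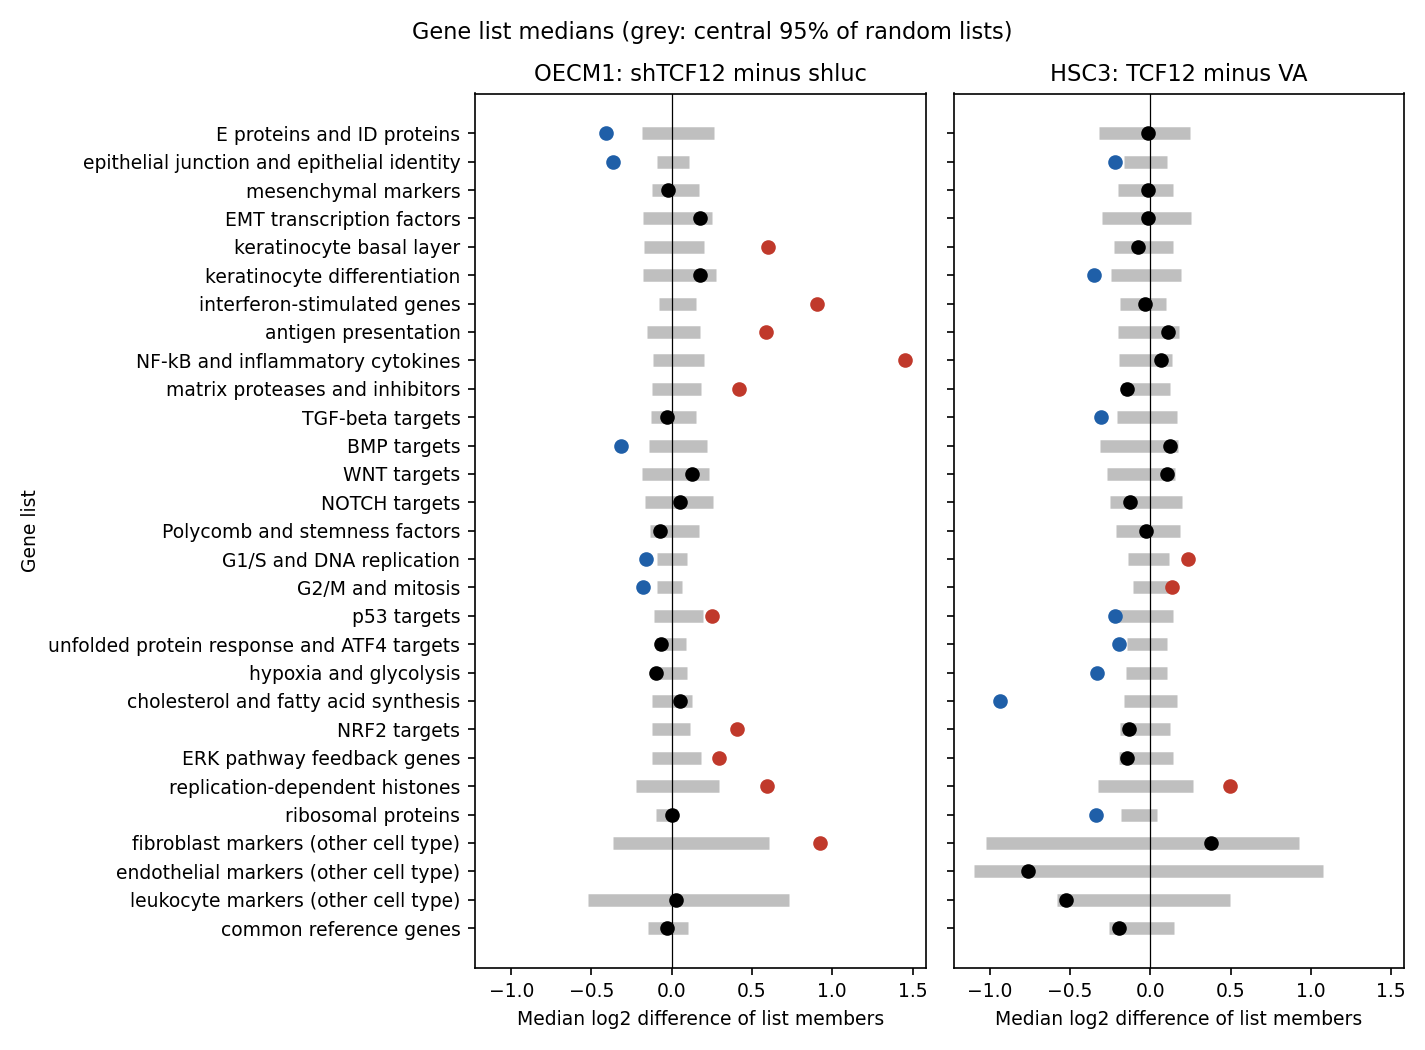
Median log2 difference of each gene list (points) in the knockdown pair and the overexpression pair, with the central 95% of random lists in grey, and red or blue points for lists standing apart higher or lower. The NF-kB list lies at 1.45 in OECM1, and cholesterol and fatty acid synthesis at -0.94 in HSC3.

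HSC3 TCF12 cells had lower transcript levels of FOSB, FOS, ATF3 and lipid synthesis genes than HSC3 VA cells. FOSB and FOS, subunits of the AP-1 factor, were at -5.08 and -4.32 on the log2 scale, with FOSB 33.9-fold lower. ATF3, a stress-induced factor, was 18.7-fold lower, and the phosphatase gene DUSP1 was 15.5-fold lower. All 3 measured probe sets of each were lower, but sizes varied, from -4.23 to -0.44 for ATF3 and from -3.96 to -0.16 for DUSP1. SCD, the stearoyl-CoA desaturase of fatty acid synthesis, was 12.5-fold lower, with all 4 measured probe sets lower. DBP, a circadian transcription factor gene, was at least 7.37-fold lower, OR4D2 at least 6.50-fold, the sodium channel subunit gene SCNN1A at least 6.30-fold, TCEA2 at least 5.38-fold and the carbonic anhydrase gene CA2 at least 3.46-fold.

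Higher in HSC3 TCF12 were PTX3, a secreted pattern recognition protein, by 12.3-fold, and LTB, encoding lymphotoxin beta, by 7.22-fold. The decoy receptor gene IL1R2 was 5.83-fold higher, the mitochondrial import gene TIMM8A 4.78-fold and CD163L1 3.88-fold. SPNS2, a sphingosine phosphate exporter gene, was at least 5.76-fold higher and the trypsin gene PRSS2 at least 5.36-fold. GPRC5B was at least 2.67-fold higher, PRSS3 at least 2.39-fold and BMP8A at least 2.32-fold. Among the genes with the largest differences in this pair, ATF3, DUSP1, SCD, DBP, PRSS2, LTB, GPRC5B and PRSS3 rest on probe sets that can bind several transcripts. The PRSS2 and PRSS3 values may therefore not be separate. Of 14630 measured genes, 474 were at least 2-fold higher and 683 at least 2-fold lower, and with the floor at the 60th percentile 136 and 326. Of 312 genes with such a difference and another measured probe set, 64.7% had all their probe sets in the same direction, against 77.0% of 379 in the knockdown pair.

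Lipid synthesis genes gave the lowest list median in the overexpression pair. Of 24 genes of cholesterol and fatty acid synthesis, 23 lay below 0 and 12 were at least 2-fold lower (median -0.94, random range -0.16 to 0.17), with the lipogenic factor gene SREBF1 at -3.25, the sterol sensor gene INSIG1 at -1.94 and the fatty acid synthase gene FASN at -1.81. Hypoxia and glycolysis genes had a median of -0.33, with 33 of 39 below 0, BHLHE40 at -1.87 and DDIT4 at -1.54. That list as fixed holds the bright gene GAPDH, so a shift of the bright range of the array may enter the list median. Targets of the unfolded protein response and ATF4 had -0.20, with ATF3 at -4.23, CHAC1 at -1.51 and PHGDH at -1.39. TGF-beta targets had -0.31 but were split, with 12 of 23 below 0 and 11 above, JUNB at -1.06 and THBS1 at 1.16. Keratinocyte differentiation genes had -0.35, with KLK10 at -2.71, KLK8 at -1.81 and SCEL at -1.72, while NOTCH3 was at least 1.36-fold higher. Without probe sets that can bind several transcripts, the TGF-beta list was inside its random range at -0.15. KLK10 then rested on a probe set close to the floor.

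Epithelial junction and identity genes were lower in HSC3 TCF12 too, with a median of -0.22 and 26 of 39 below 0 (random range -0.16 to 0.10). The list of common reference genes had nearly the same median in this pair, -0.20 with 10 of 12 below 0, inside its random range (-0.26 to 0.15). The factor gene ELF3 was at -2.10, the keratin gene KRT19 at -1.48 and the plakoglobin gene JUP at -1.05, while CDH1 was at 0.17, CLDN1 at 0.85 and GRHL3 at least 1.14-fold higher. Mesenchymal markers (median -0.02) and transcription factors of epithelial-mesenchymal transition (-0.01) lay inside their random ranges, with VIM at 0.20, FN1 at 0.10 and SNAI2 at 0.25. The 2 measured probe sets of VIM went opposite ways, the other at -1.65. So did the 2 of CDH1, with the other at -0.38, so neither gene has a clear direction in this pair. p53 targets had -0.22, with PLK3 at -1.07 and XPC at -1.02, inside the random range after quantile normalization at -0.17 and under 5 other alternatives. Ribosomal proteins had -0.34, with 35 of 36 below 0, and -0.04, inside the random range, after quantile normalization. The hybridisation spikes, added as controls, had a median difference of -0.14 in this pair and 0.05 in the knockdown pair.

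Cell cycle genes were slightly higher in HSC3 TCF12. Of 41 genes of G1/S and DNA replication, 33 lay above 0 (median 0.23), with the cyclin genes CCNE2 at 0.96 and CCNE1 at 0.58 and the replication factor gene MCM10 at 0.70. Of 48 genes of G2/M and mitosis, 35 lay above 0 (median 0.13), with ECT2 at 0.76 and ANLN at 0.64. Replication-dependent histones had a median of 0.50, with H4C8 at 0.78. The NF-kB list (0.07) and interferon-stimulated genes (-0.03) lay inside their random ranges, although PTX3 was at 3.62, C3 at 1.88 and IL1RN at -1.62. In all, 11 of 29 lists stood apart, where 1.45 would with members drawn at random. The G1/S list no longer stood apart without probe sets that can bind several transcripts (0.13), nor did the histones with the floor at the 60th percentile (0.30).

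Some genes moved oppositely with knockdown and overexpression. Of those named here, CLCA2, TUBA1A, CXCL2, GPRC5B, PDGFB, CDC42EP3 and EDEM3 rest on probe sets that can bind several transcripts. PADI3, an epidermal deiminase gene, was at least 9.93-fold higher with knockdown and 3.65-fold lower with overexpression. CLCA2, a keratinocyte adhesion gene, was at least 10.3-fold higher and 2.94-fold lower, and TNFSF10, encoding the death ligand TRAIL, was 5.52-fold higher and 2.83-fold lower. The cholesterol exporter gene ABCA1 was at 1.51 and -2.41, IL20RB at 2.00 and -1.47, PRXL2A at 3.09 and -1.43, TUBA1A at 2.77 and -1.39 and CXCL2 at 2.42 and -1.31, while NNMT and ANXA10 were at -1.64 and -1.78 in HSC3. The reverse pattern was shown by GPRC5B (-1.20, and at least 2.67-fold higher in HSC3), SPNS2 (-0.88, and at least 5.76-fold higher in HSC3), PDGFB (-0.94 and 1.18), CCNE2 (-0.85 and 0.96), CDC42EP3 (-0.79 and 0.79) and EDEM3 (-0.75 and 0.97), and by DDX11L2, MYOC, TMEM147-AS1 and BEND7.

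Across genes, the differences in the 2 pairs were nearly unrelated. Over 13239 genes measured in both, Pearson's correlation was -0.03 and Spearman's -0.05, across genes, which are not independent replicates. At the 2-fold threshold, 66 genes were higher with knockdown and lower with overexpression (23.5 expected of independent lists) and 19 the reverse (7.61 expected). In the same direction, 44 genes were higher in both (14.9 expected) and 33 lower in both (12.0 expected), so overlap above the expected number occurred in all 4 combinations. With the floor at the 60th percentile, genes lower with knockdown and higher with overexpression were down to 1, against 0.726 expected. limma called 0 of 15756 genes for a common effect of the intended TCF12 level, with a smallest adjusted p of 0.329, and 859 genes (5.45%) had an unadjusted p under 0.05.

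When both pairs were combined gene by gene, as the mean of the overexpression difference and the knockdown difference with its sign turned, 20 of 28 lists stood apart. Relative to the intended TCF12 level, whose rise in HSC3 the arrays leave open, 15 were lower and 5 higher. With members drawn at random, 1.4 would stand apart. Of the 20, 7 stood apart under every alternative run. NF-kB genes had a combined median of -0.59 (24 of 29 below 0), cholesterol and fatty acid synthesis -0.40 (22 of 24), interferon-stimulated genes -0.39 (37 of 43), NRF2 targets -0.27 (21 of 24) and ERK pathway feedback genes -0.25 (20 of 25). G1/S genes had 0.18, with 35 of 41 above 0, and G2/M genes 0.17, with 41 of 48 above 0. In the separate pairs, the cholesterol list stood apart with overexpression but not with knockdown, and the NF-kB, interferon, NRF2 and ERK lists with knockdown but not with overexpression. Keratinocyte differentiation genes had -0.47, and -0.086, inside the random range, with the mean of a gene's probe sets. Ribosomal proteins had -0.17, with 35 of 36 below 0, and -0.03, inside the random range, after quantile normalization. The other 8 lower lists had medians between -0.25 and -0.11. BMP targets (0.31) and E and ID proteins (0.18) turned to -0.071 and -0.31 with the floor at the 60th percentile. Epithelial genes had 0.074, with 20 above 0 and 17 below. They were lower in both separate pairs, and no longer stood apart on the higher side under 6 of 10 alternatives.

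**Figure D3:**
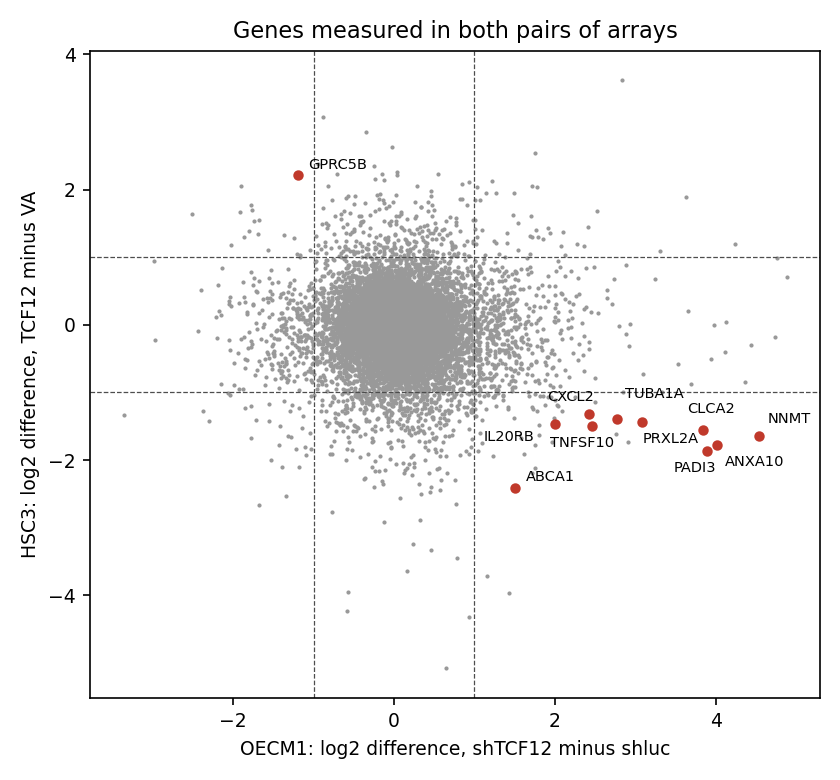
Log2 difference in OECM1 (shTCF12 minus shluc, horizontal) against HSC3 (TCF12 minus VA, vertical), 1 point per gene measured in both pairs, with dashed lines at 2-fold and labelled genes in red. Across 13239 genes the Pearson correlation was -0.03, and PADI3, NNMT and ABCA1 lie in the lower right corner.

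The control cells of the lines differed more than either manipulation, with line, vector and growth medium varying together. HSC3 VA had higher levels of basal keratinocyte genes, with KRT5 at least 443-fold higher and a list median of 2.22 over 17 members. KRT14 had an intensity of 42250 there and 54.9, at the level of the floor, in OECM1 shluc. UBB, a polyubiquitin gene, had an intensity of 35110 in HSC3 VA and 9.4 in OECM1 shluc, and was below the floor in both OECM1 arrays. The WNT inhibitor gene DKK3, the protease inhibitor gene CSTA, FABP5, IGFBP7, CCND2, MMP1 and PBDC1 were also among the 10 genes with the largest differences. OECM1 shluc had higher levels of MGP, encoding matrix Gla protein, by at least 233-fold, of the collagen gene COL5A2 by at least 145-fold and of the cancer-testis gene MAGEA6 by 116-fold. MUC4, SSX3, PLAGL1, SRGN, NR2F1, SEMA5A and ALDH5A1 were the other genes among the 10 with the largest differences on this side. Among the genes named for this comparison, DKK3, FABP5, IGFBP7, CCND2, MGP, MAGEA6, SSX3 and PLAGL1 rest on probe sets that can bind several transcripts. Of 14841 measured genes, 2098 were at least 2-fold higher in HSC3 VA and 1744 at least 2-fold lower.

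RNA quality probe sets were alike within each pair. The ratio of 3' to 5' intensity of ACTB was 1.88 in OECM1 shluc, 2.05 in OECM1 shTCF12, 2.42 in HSC3 VA and 2.26 in HSC3 TCF12, and that of GAPDH lay between 1.07 and 1.20. The ACTB 3' intensity was 42475 in HSC3 VA and 33568 in HSC3 TCF12, and the GAPDH 3' intensity was 48122.5 and 36247.7.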

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

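The comparison of gene lists that stood apart in both lines was chosen after the list medians were seen, and no difference in this part was tested, since there was 1 array per group. Of 5 such lists, 3 moved oppositely with knockdown and overexpression: p53 targets (0.25 and -0.22), G1/S genes (-0.16 and 0.23) and G2/M genes (-0.18 and 0.13). Of these, the p53 list no longer stood apart in either pair without probe sets that can bind several transcripts, and turned to -0.012 with knockdown. The G1/S list with overexpression no longer did so there either. The other 2 lists moved the same way under manipulations meant to be opposite, which a response shared by both manipulations would also give. Epithelial junction and identity genes were lower in OECM1 shTCF12 (-0.36) and also lower in HSC3 with the TCF12 vector (-0.22). In HSC3 the common reference genes had nearly the same median (-0.20), so the epithelial shift there may not be particular to these genes. Expressed as intended higher minus intended lower TCF12 level, the difference in HSC3 minus that in OECM1 was -0.59. Replication-dependent histones were higher in OECM1 shTCF12 (0.59) and higher in HSC3 TCF12 (0.50), a difference between the lines of 1.09 in the same terms. With the floor at the 60th percentile they no longer stood apart in HSC3 (0.30).

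Probe sets without a single gene name, which enter no comparison above, also differed between arrays. Of 7475 measured in the knockdown pair, 338 (4.52%) were at least 2-fold higher than in the control. Of 7432 measured in the overexpression pair, 383 (5.15%) were.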

How the results depend on the processing

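Leaving out genes above an intensity of 20000, using 100 expression bins and leaving TCF12 out of its lists were chosen after the data were seen. Median centring and quantile normalization left all counts at 2-fold within 1.5 times. The differences of the brightest TCF12 probe set held under these and other pseudocounts, the alternatives run for it, while the mean of all TCF12 probe sets gave -0.41 with knockdown and 0.13 with overexpression. Both correlations held, as did 0 calls by limma in each of its alternatives. Of 841 recomputed list medians, 768 stood apart or not as before, 51 no longer stood apart, 17 newly did and 5 turned. Of 3670 values of single genes, 3475 stayed on the same side of 2-fold. Another 126 fell below it and 48 newly reached it, in the same direction. Of the rest, 12 went from at least 2-fold to the other sign, and 9 from below 2-fold to at least 2-fold the other way. The causes of the shifts below were not tested, apart from the thresholds, which alter counts by construction.

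Genes higher and lower in the knockdown pair numbered 406 and 130 with a pseudocount of 64, 409 and 123 with the 60th percentile filter, 1829 and 1143 at 1.5-fold, and 312 and 117 at 3-fold. Genes lower numbered 840 without a filter. In the overexpression pair the numbers were 120 and 252 (pseudocount 64), 136 and 326 (60th percentile), 1344 and 1849 (1.5-fold) and 132 and 197 (3-fold). Genes higher numbered 823 without a filter and 295 with the mean of a gene's probe sets. Between the control cells they were 3739 and 3282 (1.5-fold) and 1102 and 829 (3-fold). A pseudocount of 64 put 75.7% of the differing genes of the knockdown pair on the higher side, against 65.6%.

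Counts of genes shared by both pairs moved with the pseudocount, the filter and the threshold. Lower with knockdown and higher with overexpression were 41 genes (pseudocount 1), 2 (pseudocount 64), 67 (no filter), 1 (60th percentile), 111 (1.5-fold) and 5 (3-fold), where 13.2, 0.862, 35.0, 0.726, 71.6 and 0.508 were expected of independent lists. Higher and then lower were 103, 22, 109, 28, 305 and 11 (36.3, 5.53, 59.6, 7.00, 169 and 2.06 expected), and 38 with the mean of probe sets (11.2). Lower in both were 54, 4, 70, 6, 172 and 2 (19.6, 1.92, 41.4, 2.03, 105 and 0.821). Higher in both were 68, 14, 95, 18, 205 and 7 (24.4, 2.48, 50.3, 2.51, 115 and 1.27), and 26 with the mean of probe sets (5.94).

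Some list medians turned. Combined over both pairs, the E and ID protein median became -0.31 and the BMP median -0.071 with the 60th percentile filter. Without probe sets that can bind several transcripts, the combined medians of mesenchymal markers and matrix proteases became 0.0046 and 0.0072, and the p53 median with knockdown -0.012. Of the 12 single-gene values that turned, 10 came from 1 dim probe set each, with no intensity above 71.6. Of these, 4 lay below the floor on both arrays and set no direction. The other 6 lay above it on at least 1 array, close enough to it that their direction is uncertain. Without probe sets that can bind several transcripts the values were -0.95 for AKR1C2, -0.075 for COL6A1, 0.092 for HABP4 and -0.047 for S100A8 with knockdown, and -0.26 for CDH11, 0.023 for GDF15 and 0.44 for KLK10 with overexpression. The mean of probe sets gave -0.080 for MMP2 with knockdown and -0.11 for ZEB1 with overexpression. A pseudocount of 1, which selected another probe set, gave -0.66 for PBDC1 with knockdown, and -0.051 for PLAGL1 and -0.74 for ZEB1 with overexpression.

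No replicate numbers pair the arrays, and leaving out an array ends its comparison. The limma model holds cell line as a block. Genes near the floor have little signal over background, which limits their differences.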

Other observations

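All tests in this part were chosen after the result was seen, except the one on neighbouring genes, and the genes of the next paragraph were chosen after their values were seen.

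Over 14 immediate early genes the median in HSC3 TCF12 was -1.52, with 10 at least 2-fold lower. These include FOSB, FOS, ATF3, DUSP1 and JUNB, already named. The other 9 had a median of -1.03, with 5 at least 2-fold lower, NR4A1 at -2.45, EGR1 at -2.15, ZFP36 at -1.83, KLF4 at -1.20 and IER2 at -1.03. In OECM1 shTCF12 the 14 had a median of 0.40. IFI16, a DNA sensor gene, was at 3.99 and SLPI, a secreted protease inhibitor gene, at 2.34 in OECM1 shTCF12. Of 9 measured genes of the PSG family, 8 lay below 0 there and 3 were at least 2-fold lower, PSG7 with PSG4 at -1.75 and PSG9 at -1.32, while PSG2 lay above 0. Their probe sets can bind several members of the family.

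The higher inflammatory and interferon genes in OECM1 shTCF12 were weighed against 3 explanations. RNA of HSC3 cells in the sample would bring the abundant HSC3 transcripts, but 26 genes above 2000 in HSC3 VA and at the floor in OECM1 shluc reached a median of 0.245% of their HSC3 level, while the 39 higher genes would need a median of 262%. Scaling between arrays is also argued against, since the NF-kB median was 1.43 after quantile normalization. The control also carried a hairpin, so an innate response common to any hairpin would be in both samples. An innate response particular to this hairpin or to the dose of virus cannot be told apart from an effect of TCF12. There was a single hairpin against TCF12, and the higher interferon-stimulated genes (0.90) are part of the pattern itself. An effect of TCF12 on these genes may therefore be only 1 of the open explanations. RNA of a cell type other than HSC3 was not weighed here, although the fibroblast list stood apart on the higher side in this pair (0.92 over 7 measured members).

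The lower ribosomal protein genes in HSC3 TCF12 may come in part from compression of the bright range of that array. The 4 cre hybridisation spikes, as bright as these genes, had a median difference of -0.24, and quantile normalization moved the ribosomal list inside its random range. The dimmer bioB and bioC spikes had -0.11 and the poly-A spikes -0.13, so part of the cre difference may not be specific to the bright range. No biological explanation was tested.

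The lower lipid synthesis and immediate early genes in HSC3 TCF12 do not follow that compression, since their median over 38 genes was -1.10 after quantile normalization and -1.12 before. The state of the culture at harvest, such as serum or density, could lower both groups together. The count made for it, 12 lipid genes at least 2-fold lower, is the pattern itself and decides nothing about the culture. The state of the culture cannot be told apart from an effect of the vector, because each group was 1 culture.

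A hypothesis that broad copy number differences between subclones account for the genes differing within each line was tested by counting pairs of genes 5 to 20 places apart on a chromosome that differed the same way. The ratio to 100 shuffled gene orders was 1.02 in the knockdown pair and 1.04 in the overexpression pair, where a ratio above 1.5 in both had been set as the mark of such differences. Between the control cells of the lines it was 1.21, below that mark, although the 9448 pairs lay outside the shuffled range of 7691 to 8012. The 946 pairs of the knockdown pair lay inside theirs (862 to 1037), as did the 771 of the overexpression pair (683 to 811). Since the mark was missed even between the lines, missing it within a line cannot exclude broad copy number differences. Small segments and shifts below 2-fold were also left unexamined.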
